A study of Mus musculus with 23 samples.

How the data were processed

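RNA was sequenced from a mouse myeloid progenitor line in which both copies of Cebpa can make only p30, the shorter form of the transcription factor C/EBPα, a model of acute myeloid leukaemia (AML). Per the labels' protocols, cells were grown with 10% serum, 2 mM glutamine and 5 ng/mL interleukin 3, and received 1 µg/mL doxycycline for 48 h before harvest. The 6 RNA libraries carried either a control hairpin (shRen, n = 3) or a hairpin against Cebpa (shCebpa, n = 3). The titles and source names of the 3 shCebpa RNA libraries also contain the word shRen, and only the library name in brackets says shCebpa. Groups were therefore taken from the bracketed names, and the level of Cebpa in each library is reported first as a check of the labels. The series holds 23 samples. The other 17 are 6 H3K27ac and 8 C/EBPα chromatin immunoprecipitation libraries, inputs included, and 3 ATAC libraries, and they were not analysed here.

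The deposited values are a signal per gene, namely read counts that the authors divided by a size factor for each library, as the values themselves show. The submitters' processing notes name STAR 2.5.0b, featureCounts 1.6.0, DESeq2 1.26.0 and the mouse build mm10 without saying what each was used for. How reads that map to several places were treated, whether counting used strand, and any filter are not given in the sources used here. Reads from near-identical genes, pseudogenes or overlapping genes may thus have been split or left uncounted. In every library 100.0% of the nonzero values were whole multiples of what 1 read was worth, within a tolerance of 0.001 read, so whole reads were recovered. The recovered totals were 17554604, 16755654 and 19736954 reads for shRen replicates 1, 2 and 3, and 17779036, 14560647 and 15862006 reads for shCebpa replicates 1, 2 and 3. The deposited size factors matched median-of-ratios factors computed from the recovered reads to within 0.22% after a common scale was removed.

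The table holds 24454 Entrez gene IDs. Of these, 24376 were given a symbol from the RefSeq annotation of GRCm38.p6, the assembly behind mm10, and 78 were not. The most abundant row is among the unnamed IDs and took 1.22% to 1.67% of the reads of a library.

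The analysis plan foresaw counts or normalized values. Because the table held size-factor-scaled values and not counts, the test planned for normalized values was the main test. Values were transformed as log2(value + 1), and 13712 genes with a mean value of at least 1 were tested with limma 3.58.1, with a trend of the variance on the mean, in R 4.3.3. Two-sided p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called changed. Log2 fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. A change given as N-fold for a gene is the ratio of the group means of the deposited values, with nothing added, and so can exceed the log2 fold change of the same gene. Counts of genes changed by at least 2-fold use instead an absolute log2 fold change of at least 1 on the log2(value + 1) scale. Adjusted p-values in the report are from limma unless another tool is named. Counting error and the spread between libraries together gave a median standard error of 0.088 on the log2 scale.

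Genes were named by a rule set before the data were examined. The rule took Cebpa and Msi2. It then took the 10 largest rises and the 10 largest falls among changed genes with a mean log2 CPM of at least 1 and no overlap between the groups. Finally it took up to 4 members of each gene list with the smallest adjusted p. Members named beyond this rule, mainly where a list had few members in a class, were chosen after their values were seen. The 29 gene lists were also fixed beforehand. Of these, 28 were tested, and the list of mitochondrially encoded genes had no matched ID and was not analysed here. Another 2 symbols, Ighm and Chop, had no match. Lists were tested with camera (limma), with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. The test was repeated with a correlation estimated for each list and with fry.

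The alternatives were edgeR 4.0.16 quasi-likelihood tests on the recovered reads, DESeq2 1.42.0, limma-voom, other scaling factors, other filters, pseudocounts of 0.1 and 5, the replicate number as a block, and leaving out each library. Rescaled limma values, edgeR with TMM factors, removal of a length and GC trend, and lists without shared members were added after the data were seen. On data simulated from the shCebpa and shRen libraries with 13710 genes tested, limma recovered 62% of 50 genes changed 1.25-fold, 88% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. In that simulation 3.35% of calls were false. The changed genes were drawn from genes well above the filter of the main test, so recovery of genes with few reads was not simulated. Far fewer genes were changed there than were called in the real data, so these shares may not carry over. Sequence features came from GRCm38.p6. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the remaining steps.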

Results

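The RNA libraries addressed which genes depend on p30 C/EBPα in leukaemic myeloid progenitors, a question the series title links to Msi2. Gene-level read counts scaled by library size factors were compared between 3 shCebpa and 3 shRen libraries of 14560647 to 19736954 assigned reads. Every pair of replicates differed by more than counting noise, with a chi-square per gene between 2.91 and 6.75, and none were treated as copies of one library. The labels do not say that replicates were separate cultures, and p-values then measure only the spread between these samples, which may be technical.

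Cebpa, the gene that the hairpin targets, was lower in all 3 shCebpa libraries. Its size-factor-normalised read count was 4189.8, 4598 and 4120.5 in shRen replicates 1, 2 and 3, and 1029.7, 891.5 and 982.55 in shCebpa replicates 1, 2 and 3. The mean fell from 4303 ± 258 to 968 ± 70.3 (SD, n = 3 each), to 22.5% of the shRen level. The log2 fold change was -2.15 with a standard error of 0.06 (limma, adjusted p = 9.75e-14). An exact two-sided permutation test over the 20 assignments gave p = 0.1, the smallest that 3 against 3 libraries allow. Cebpa (Entrez 12606) is a gene of 1 exon on the plus strand of chromosome 7, at 35119293 to 35121928 in GRCm38. The values go with the bracketed shCebpa and shRen names.

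Msi2, which encodes an RNA-binding protein of stem and progenitor cells, fell to 47.9% of its shRen level. Its mean was 2689 ± 156 in shRen and 1287 ± 3.35 in shCebpa (SD, n = 3 each), a log2 fold change of -1.06 with a standard error of 0.05 (limma, adjusted p = 1.1e-10). The exact permutation p was again 0.1. Msi2 (Entrez 76626) has 15 annotated exons on the minus strand of chromosome 11, at 88339382 to 88718306. The series title names Msi2, so its direction here is not taken as independent evidence.

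**Figure D1:**
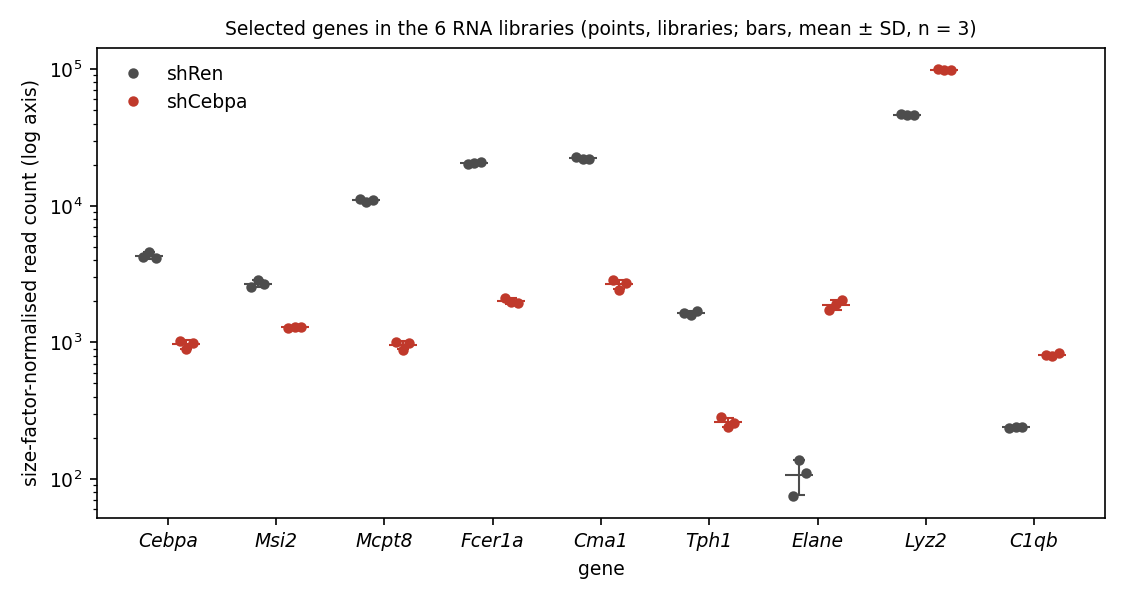
Size-factor-normalised read counts (log axis) of 9 genes in the 3 shRen (grey) and 3 shCebpa (red) libraries; points are libraries and bars are mean ± SD, n = 3. Cebpa, Msi2 and the mast cell and basophil genes Mcpt8, Fcer1a, Cma1 and Tph1 were lower in every shCebpa library than in any shRen library, and Elane, Lyz2 and C1qb were higher.

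Knockdown of Cebpa was accompanied by a broad change of the transcriptome. Of 13712 genes tested, 5973 changed (43.6%), with 2935 higher and 3038 lower in shCebpa. Which side was larger depended on the settings: 49.1% of calls were rises here, 54.6% with library-total scaling and 56.6% with a length and GC trend removed. A change of at least 2-fold, taken as an absolute log2 fold change of at least 1, was estimated for 1174 of them, 504 higher and 670 lower. The median absolute log2 fold change of changed genes was 0.41. The first principal component held 66.0% of the variance and separated the groups. Correlations across genes were 0.990 to 0.992 within groups and 0.971 to 0.972 between them. In 6988 genes (51.0%) the groups did not overlap, against 10% by chance for 3 against 3 libraries. At an unadjusted p under 0.05, 6912 genes passed. The edgeR test on recovered reads called 5881 of 11674 genes, shared 5666 calls with limma and gave none of these the opposite direction.

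The largest rise among the genes taken by the naming rule was that of Elane, neutrophil elastase, a protease of primary granules. Its level rose from 107 ± 31.4 to 1892 ± 160 (SD, n = 3 each), or 17.6-fold. Marcks, a substrate of protein kinase C, rose 12.7-fold, the protease inhibitor Serpinb2 12.1-fold, the macrophage lectin Mgl2 11.7-fold and the myosin light chain kinase Mylk 10.4-fold. The circadian transcription factor Npas2 rose 7.54-fold, Susd4 7.23-fold, the protocadherin Pcdh7 7.09-fold, the innate immune kinase Alpk1 6.88-fold and the RNA-binding protein Igf2bp3 5.59-fold. Their log2 fold changes lay between 2.48 for Igf2bp3 and 4.17 for Elane, and the highest adjusted p among them was 1.49e-09 (limma, Pcdh7).

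The largest falls were steeper than these rises. B4galt6, a galactosyltransferase of glycolipid synthesis, fell from 736 ± 29.9 to 13.02 ± 1.6 (SD, n = 3 each) and was 56.6-fold lower in shCebpa. The glycosyltransferase gene Large1 was 56.4-fold lower, the interleukin 25 receptor subunit Il17rb 39.0-fold, the ubiquitin ligase Rnf144b 33.2-fold and Fam217b 30.3-fold. Gpm6a was 27.7-fold lower, the glycosyltransferase Galnt6 25.8-fold, the actin regulator Avil 21.4-fold, Flot2 20.4-fold and the actin nucleator Cobl 18.3-fold. Avil was the most abundant of the 10, with 3441 ± 79.2 in shRen and 161 ± 11.2 in shCebpa. The highest adjusted p among them was 4.36e-09 (limma, Fam217b).

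**Figure D2:**
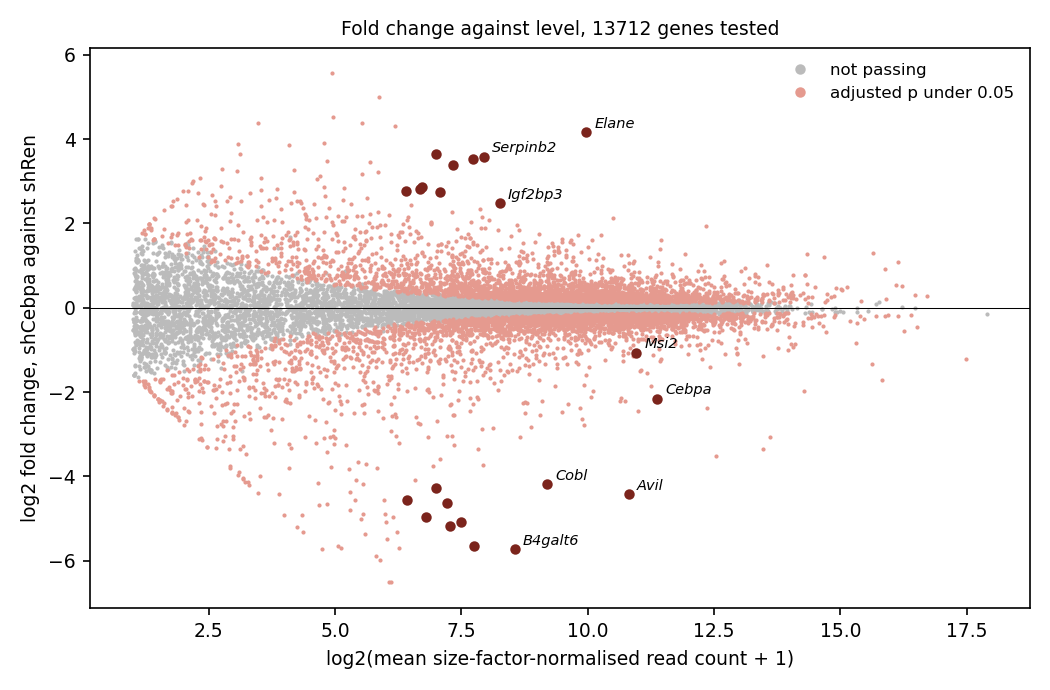
Log2 fold change of shCebpa against shRen (on log2(value + 1)) plotted against the log2 of the mean size-factor-normalised read count plus 1 for 13712 genes; red points passed an adjusted p of 0.05 and dark points are Cebpa, Msi2 and the 20 genes with the largest changes under the naming rule, of which 8 are labelled. Genes changed in both directions over the whole range of levels, with 2935 higher and 3038 lower.

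Genes of mast cells and basophils fell together. Of the 18 listed, 16 fell, 1 rose and 1 did not pass, with the same counts adjusted over the list alone. The median log2 fold change was -1.17. Mcpt8, a basophil protease, fell from 11010.0 ± 243 to 959 ± 71.3 (11.5-fold lower). Fcer1a, the IgE-binding subunit of the high-affinity IgE receptor, was 10.2-fold lower, the chymase Cma1 8.36-fold and Tph1, which makes serotonin, 6.25-fold. Tpsab1, a tryptase gene with a related gene beside it, rose (log2 fold change 0.69), and how reads shared by related genes were counted is not given. Mcpt4 had a log2 fold change of -0.11 without passing. The list was lower by camera (limma) with an adjusted p of 4e-15, and adjusted p = 0.11 with an estimated correlation.

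Eosinophil genes moved in both directions, and the list did not pass (adjusted p = 0.0569, camera), although it passed in all 5 edgeR settings (0.0265 to 0.0268), without shCebpa replicate 1 (0.0435) or 3 (0.0402), with library-total scaling (0.0439), with no filter (0.0482) and with the length and GC trend removed (0.0288). Of 8 members, 5 fell, among them the interleukin 5 receptor subunit Il5ra (3.21-fold lower) and the granule protein Prg2 (2.25-fold lower), with Ccr3, Prg3 and Ptger3. The lipoxygenase Alox15 and the peroxidase Epx rose, and Siglecf had a log2 fold change of -0.05. Counts adjusted over the list alone were the same.

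Monocyte and macrophage genes were mostly higher. Of 41 tested, 22 rose, 10 fell and 9 did not pass (23 rose and 10 fell when adjusted over the list alone). The complement gene C1qb rose from 239 ± 2.85 to 812 ± 22.7, or 3.4-fold, Gpnmb rose 3.04-fold and lysozyme 2 (Lyz2) rose from 46430.0 ± 342 to 99020.0 ± 914. Reads of Lyz2 and its near copy Lyz1 may not be separable. Ccr2, the receptor that brings monocytes out of the marrow, went the other way and was 2.64-fold lower. The list was higher with an adjusted p of 1.3e-04 (camera), and adjusted p = 0.158 with an estimated correlation.

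The granulocyte lists did not move as a unit. Of 15 primary granule genes, 7 rose, 5 fell and 3 did not pass, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.504, camera), although it passed in all 5 edgeR settings (0.0296 to 0.036). Beside Elane, the protease Prtn3 rose 2.11-fold and haptoglobin (Hp) 1.82-fold, whereas Plac8 fell from 52070.0 ± 1115 to 29290.0 ± 1997. The other 4 that fell were Serpinb1a, Prss57, Nkg7 and Calr, and Ap3s1, Cst7 and Ms4a3 had log2 fold changes of -0.15, -0.09 and 0.05. Of 30 late granule and neutrophil genes, 8 rose and 16 fell, over all genes and adjusted over the list alone. Ngp, a secondary granule protein, was 3.94-fold lower, the histone-modifying enzyme Padi4 2.01-fold and lactoferrin (Ltf) 1.96-fold. Stfa2, which was 2.11-fold lower, belongs to a family of near-identical genes and is uncertain. This list was lower with an adjusted p of 0.0134 (camera), and adjusted p = 0.158 with an estimated correlation.

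More inflammatory and immediate early genes rose than fell. Of 28 NF-kB and cytokine genes, 17 rose and 4 fell (Ccl2, Ier3, Il6 and Cxcr4), with the same counts adjusted over the list alone. Il6 lost its call without shRen replicate 3 (adjusted p = 0.0691, limma), without shCebpa replicate 1 (0.0548) and with the length and GC trend removed (0.955). The chemokine Ccl6 rose from 29480.0 ± 316 to 72610.0 ± 486, tumour necrosis factor (Tnf) rose 2.51-fold, Ccl4 2.49-fold and Ccl3 2.39-fold. The list was higher with an adjusted p of 2.83e-06 (camera), and adjusted p = 0.158 with an estimated correlation. Of 21 immediate early and AP-1 genes, 15 rose and 2 fell (Etv4 and Klf6), again with the same counts adjusted over the list alone. Etv4 lost its call without shRen replicate 1 or 2 or shCebpa replicate 2 (adjusted p = 0.0593 to 0.0784, limma), which left 1 fall, and Klf6 with the length and GC trend removed (0.113). The transcription factor gene Egr1 rose 2.97-fold, Egr2 2.93-fold and the phosphatase Dusp2 2.87-fold. Klf2, Nr4a1, Fosb and Fosl1 did not pass, with log2 fold changes of -0.01, 0.16, 0.31 and 0.51. This list was higher with an adjusted p of 5.47e-06 (camera), and adjusted p = 0.182 with an estimated correlation.

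Interferon response genes split, with more rises than falls. Of 33, 15 rose and 5 fell (16 and 5 adjusted over the list alone). Ifi203 rose 2.8-fold, the chemokine Cxcl10 2.49-fold and the antiviral membrane protein Bst2 2.26-fold. The genes that fell were Zbp1, Isg20, Stat2, Irgm1 and Stat1. Stat1 lost its call without any of 5 libraries, all but shCebpa replicate 2 (adjusted p = 0.0719 to 0.12, limma), and with library-total scaling (0.105). The list was higher with an adjusted p of 0.0134 (camera), and adjusted p = 0.158 with an estimated correlation. Of 17 dendritic cell and MHC class II genes, 5 rose (Itgax, Bst2, H2-DMa, Cd74 and Irf4) and H2-Aa fell, with the same counts adjusted over the list alone. H2-Aa lost its call without shRen replicate 1 or 2 or shCebpa replicate 3 (adjusted p = 0.0535 to 0.0926, limma). That list did not pass (adjusted p = 0.0869, camera). It passed in all 5 edgeR settings (0.00748 to 0.00951), which tested 13 of its members. It also passed under both stricter filters (0.0469 and 0.0434) and without shCebpa replicate 2 (0.042).

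More replication and ribosome biogenesis genes rose than fell. Of 32 DNA replication and E2F genes, 17 rose and 0 fell by limma, over all genes and adjusted over the list alone, with 0 lower at an unadjusted p under 0.05 and 0 by edgeR, and 1 fell without shCebpa replicate 2. The median log2 fold change of the list was 0.16. The transcription factor E2f2 rose 2.24-fold, Ccne1 (cyclin E1) 1.56-fold and the licensing factor Cdt1 1.52-fold. Of the rises, those of Mcm2, Mcm7, Cdc6, Rrm2, Pole and Cdc45 each lost their call without at least 1 library (adjusted p = 0.0584 to 0.188, limma). Cdc6 lost it without any of 5 libraries. This list had an adjusted p of 7.18e-04 (camera), and adjusted p = 0.187 with an estimated correlation. Of 32 MYC target and ribosome biogenesis genes, 17 rose and 3 fell (18 and 3 adjusted over the list alone). Spermidine synthase (Srm) rose 1.53-fold and the nucleolar protein Nop56 1.44-fold, and Wdr12, Npm1 and Hspe1 fell. Hspe1 lost its call without shRen replicate 1 or 3 or shCebpa replicate 3 (adjusted p = 0.0507 to 0.0798, limma), and the other 2 lost theirs once a length and GC trend was removed (0.0588 for Wdr12 and 0.134 for Npm1). This list had an adjusted p of 2.35e-04 (camera), and adjusted p = 0.344 with an estimated correlation. Of 25 mitosis genes, 11 rose, among them Aurkb (log2 fold change 0.32), and Kif23 fell (12 and 1 adjusted over the list alone). These counts depended on single libraries: 5 rose without shRen replicate 1, 6 without shRen replicate 2 and 5 without shCebpa replicate 3, and Kif23 lost its call without shRen replicate 1 or 3 or shCebpa replicate 1 or 3 (adjusted p = 0.0509 to 0.137, limma), while 2 fell without shCebpa replicate 2. The mitosis list did not pass (adjusted p = 0.0569, camera), but passed without shRen replicate 3 (0.0141), without shCebpa replicate 1 (0.0164), scaled by library totals (0.0366), with no filter (0.0381) and with the length and GC trend removed (8.05e-04).

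Metabolic and stress lists moved apart. Of 21 cholesterol synthesis genes, 13 fell and 0 rose by limma (14 and 0 adjusted over the list alone), with 0 higher at an unadjusted p under 0.05 and 0 by edgeR. Cyp51 was 1.77-fold lower, HMG-CoA synthase (Hmgcs1) 1.6-fold and lanosterol synthase (Lss) 1.47-fold. The list was lower with an adjusted p of 4.76e-05 (camera), and adjusted p = 0.11 with an estimated correlation. Of 21 ATF4 and unfolded protein response genes, 12 rose and 0 fell by limma (12 and 1 adjusted over the list alone), with 1 lower at an unadjusted p under 0.05 and 1 by edgeR, and 2 fell without shCebpa replicate 2. The transcription factor Atf5 rose 4.11-fold, Chac1, which degrades glutathione, 3.79-fold and the folate enzyme Mthfd2 1.71-fold. The list had an adjusted p of 1.99e-04 (camera), and adjusted p = 0.187 with an estimated correlation. Of 27 lysosome genes, 15 rose and 4 fell (16 and 5 adjusted over the list alone). Cathepsin Z (Ctsz) rose 2.06-fold and prosaposin (Psap) 1.88-fold, whereas Npc2, Cd63, Ctsc and Laptm5 fell. Laptm5 lost its call without any 1 shRen library (adjusted p = 0.0663 to 0.0693, limma), and Ctsc with the length and GC trend removed (0.986). The list had an adjusted p of 0.00124 (camera), and adjusted p = 0.421 with an estimated correlation.

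Stem and progenitor genes went both ways. Of 30, 8 rose and 13 fell (8 and 14 adjusted over the list alone), and the list did not pass (adjusted p = 0.359, camera). Cd34 rose from 3190.0 ± 92.7 to 6465 ± 233, whereas the transcription factor Ikzf2 was 2.33-fold lower and Ly6a 2.19-fold. Among 14 genes linked to p30 in earlier work, 6 rose and 4 fell (7 and 4 adjusted over the list alone). The granulocyte colony-stimulating factor receptor Csf3r rose 4.01-fold and Myc 1.42-fold, whereas Gata2 was 1.23-fold lower, with falls of Msi2, Sox4 and Tet2 beside it. Tet2 lost its call without shRen replicate 1 (adjusted p = 0.0631, limma) and with the length and GC trend removed (0.0736). Nt5e, Wdr5, Kdm1a and Cebpe had log2 fold changes of -0.18, -0.07, -0.01 and 0.15. The series title names Msi2, so this list is not taken as independent evidence, and it did not pass (adjusted p = 0.558, camera). In the family of Cebpa and its regulators, 3 of 10 rose and 2 fell (4 and 2 adjusted over the list alone). Cebpb rose 2.29-fold, the pseudokinase Trib3 2.2-fold and Cebpd 1.38-fold, and Cebpz fell with Cebpa. Cebpz lost its call without shRen replicate 3 or shCebpa replicate 1 or 3 (adjusted p = 0.0555 to 0.0682, limma), which left 1 fall, and with the length and GC trend removed (0.546). Cebpg, Cop1, Ddit3, Cebpe and Trib1 did not pass, with log2 fold changes of -0.16, -0.13, 0.06, 0.15 and 0.24, nor did the list (adjusted p = 0.696, camera).

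Of 23 myeloid cytokine receptors, 11 rose and 7 fell, with the same counts adjusted over the list alone. Csf2ra rose 2.43-fold, the tumour necrosis factor receptors Tnfrsf1b and Tnfrsf1a 2.17-fold and 2.1-fold, and Csf1r 1.6-fold. Flt3, Il3ra, Tgfbr1, Il4ra and Il1r1 did not pass, with log2 fold changes of -0.34, -0.02, 0.02, 0.06 and 0.58, nor did the list (adjusted p = 0.0597, camera). It passed in all 5 edgeR settings (0.00251 to 0.00429), under the 3 other filters (0.0442 to 0.0469), without members that other lists hold (0.0465), and without shRen replicate 2 (0.0396) or shCebpa replicate 2 (0.027). Of 19 NADPH oxidase and phagocytosis genes, 8 rose and 4 fell over all genes and adjusted over the list alone, and the list did not pass (adjusted p = 0.147, camera), except without shCebpa replicate 2 (0.0465). The metal transporter Slc11a1 rose 1.75-fold, whereas Cybb, the catalytic oxidase subunit, was 1.64-fold lower, and Itgal, Tyrobp and Rac2 also fell. Tyrobp and Rac2 lost their calls without shRen replicate 1 or 2 (adjusted p = 0.0542 to 0.115, limma), which left 2 falls, and Tyrobp also without shCebpa replicate 2 (0.0689).

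Markers of other lineages moved in both directions, and their lists did not pass in the main test. Of 12 erythroid genes, 2 rose (Car2 and Alas2) and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.794, camera). Gata1 was 2.61-fold lower and Tfrc 1.46-fold. Alas2 lost its call without shRen replicate 2 or any 1 shCebpa library (adjusted p = 0.0612 to 0.123, limma), which left 1 rise. Epor was close to the detection floor, at 4.17 ± 3.06 in shRen and 0.338 ± 0.585 in shCebpa, and lost its call without shRen replicate 2 (adjusted p = 0.128) and without shCebpa replicate 3 (adjusted p = 0.0595). Of 18 megakaryocyte and platelet genes, 5 rose and 5 fell over all genes and adjusted over the list alone (adjusted p = 0.794, camera), and the sign of the list median changed with the scaling. Ppbp rose 3.09-fold and Pf4 2.13-fold with Gp6, Treml1 and Tubb1, and Rab27b was 2.4-fold and Gp5 3.13-fold lower, with falls of Gp1bb, Gp1ba and Itgb3. Gp6 lost its call without shRen replicate 3 (adjusted p = 0.0643, limma) and without shCebpa replicate 1 (0.085). Of 11 lymphoid genes, 2 rose (Il7r and Blnk) and 5 fell, with the same counts adjusted over the list alone (adjusted p = 0.0948, camera). The list was lower in all 5 edgeR settings (0.00748 to 0.00951), but these tested only 6 of its members. Cd7 was 4.65-fold lower, Lck 2.7-fold and Tcf7 2.1-fold, Cd79b fell as well, and Rag2 fell to 0 reads in every shCebpa library. With a mean value of at least 5 required, 7 members were tested and 4 fell, so the 5 falls include that of a gene with few reads. Vpreb1, Cd3d, Igll1 and Cd79a had log2 fold changes of -0.65, -0.44, -0.03 and 0.22. Of 9 stromal, endothelial and epithelial genes, 4 rose (Pdgfrb, Thy1, Acta2 and Col4a2) and 3 fell (5 and 4 adjusted over the list alone). Without shCebpa replicate 1 only 2 rose, as Pdgfrb (adjusted p = 0.0546, limma) and Acta2 (0.0698) lost their calls, and Pdgfrb also lost its call without shRen replicate 3 (0.104) or shCebpa replicate 3 (0.0684). The adhesion genes Cdh1 and Epcam were 2.94-fold and 2.54-fold lower and Pecam1 1.28-fold, and Tek and Col1a1 had log2 fold changes of -1.39 and 1.07 without passing over all genes. In that list the median (0.22) and the test (down, adjusted p = 0.755, camera) differed in sign, and fry gave an adjusted p of 2.57e-04 downward.

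Of 27 chromatin regulators mutated or targeted in AML, 6 rose and 6 fell over all genes and adjusted over the list alone. The methylcytosine dioxygenase Tet1 was 3.24-fold lower and the DNA methyltransferase Dnmt3a rose 1.43-fold. The list did not pass (adjusted p = 0.794, camera), with a median of 0.01 and a mean of -0.03. Of 23 p53 targets and CDK inhibitors, 7 rose and 8 fell over all genes and adjusted over the list alone, and the sign of the list median changed with the scaling (adjusted p = 0.794, camera). Cdkn1a rose 1.67-fold and Cdkn2b was 2.22-fold lower. Of 18 replication-dependent histone genes, a sign of RNA selection, H2bc4 and H1f2 fell and 0 rose by limma (1 and 0 adjusted over the list alone), with 1 higher at an unadjusted p under 0.05 and 0 by edgeR. That list did not pass (adjusted p = 0.755, camera). H1f2 lost its call without shRen replicate 2 (adjusted p = 0.0939) and without shCebpa replicate 3 (adjusted p = 0.0546), which left 1 fall. Of 15 reference genes, 4 rose (Pgk1 1.62-fold, Actb 1.22-fold, Tubb5 1.13-fold and Ppia) and 2 fell (Hprt 1.17-fold lower, and Eef2), over all genes and adjusted over the list alone (adjusted p = 0.669, camera). Hprt went from a log2 fold change of -0.22 to -0.05 and lost its call once the length and GC trend was removed (adjusted p = 0.528, limma). Tubb5 lost its call without shRen replicate 1 (adjusted p = 0.0517), as did Ppia, which left 2 rises; Ppia also lost it without shRen replicate 3 or shCebpa replicate 1 or 2 (adjusted p over the 4 libraries 0.0509 to 0.216). Eef2 lost its call without shRen replicate 1 or 2 or shCebpa replicate 3 (0.0558 to 0.164), which left 1 fall.

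**Figure D3:**
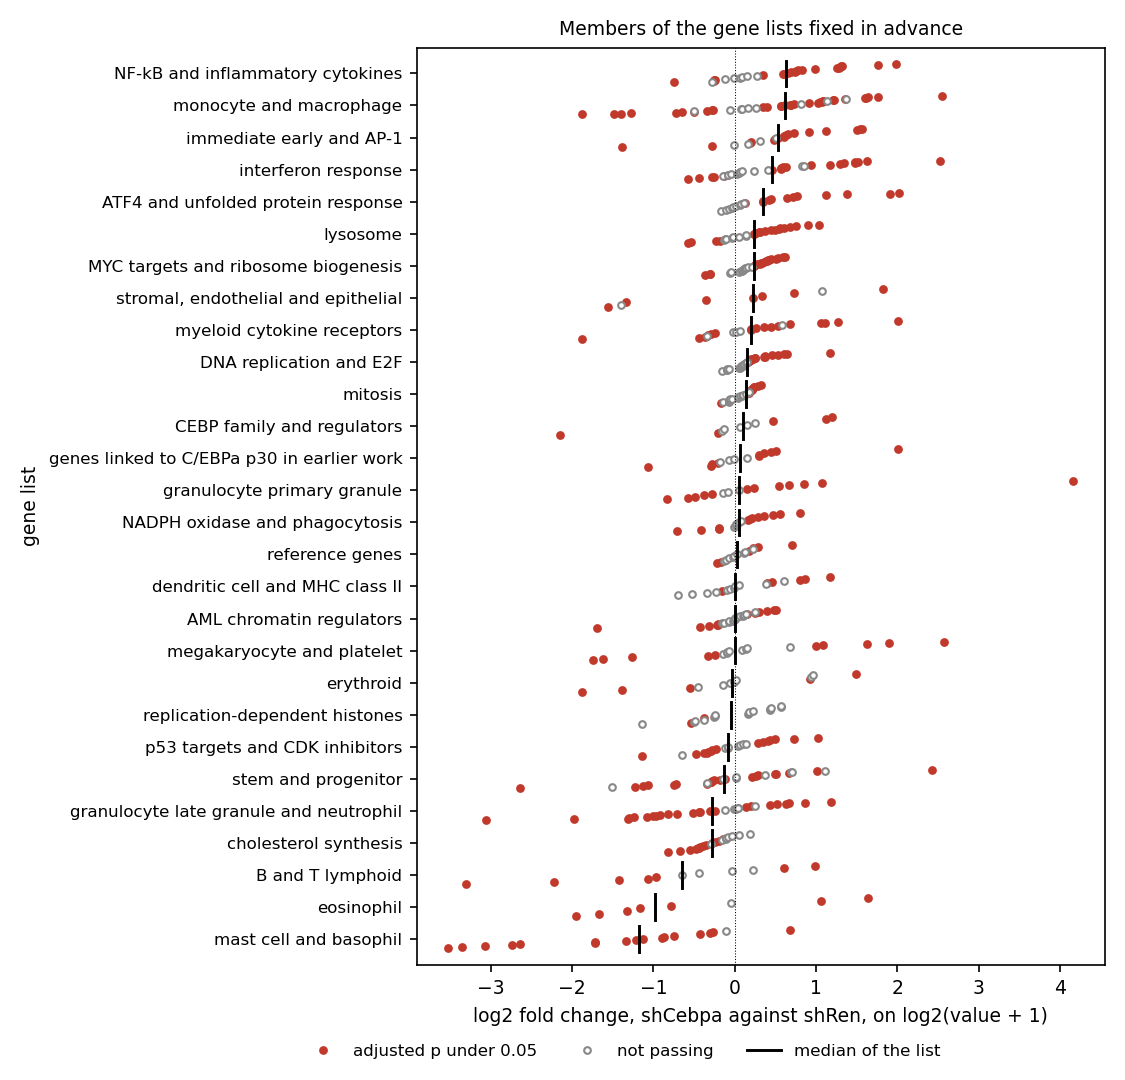
Log2 fold change of shCebpa against shRen (on log2(value + 1)) of the tested members of 28 gene lists; each point is a gene, filled where its adjusted p was under 0.05 (limma), and black bars are list medians. Of the mast cell and basophil genes, 16 of 18 fell, and of the monocyte and macrophage genes 22 of 41 rose.

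In all, 11 of the 28 lists passed with the preset correlation. With an estimated correlation 0 passed by camera, and 7 had an unadjusted p under 0.05. The fry test, which asks only whether members of a list move one way on balance, passed 20, and camera passed 16 in each of the 5 edgeR settings. In other divisions of the same 6 libraries into 3 and 3, the preset-correlation test passed up to 8 lists. Each of those divisions holds both groups on each side in unequal numbers, so part of the group difference remains in it. They thus give no background level for the 11 lists.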

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

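The added alternatives (edgeR with TMM factors, rescaled limma values, removal of a length and GC trend, and lists without shared members) and the tests of other splits of the gene counts and of that trend were chosen after the results were seen. Over 23 alternatives the count of changed genes lay between 4864 and 6475, against 5973, and both ends came from leaving out 1 library (shRen replicate 3 and shCebpa replicate 2). Rises numbered 2384 to 3250 and falls 2294 to 3337, and the side with more calls changed: 49.1% of calls were rises in the main test, 54.6% with limma and 55.1% with edgeR on library totals, 52.997% with edgeR on upper-quartile factors, and 56.6% with the length and GC trend removed. The log2 fold change stayed between -2.35 and -2.09 for Cebpa and between -1.1 and -0.98 for Msi2, and both passed throughout, with highest adjusted p-values of 6.56e-11 and 1.54e-08. The count of genes lower by at least 2-fold was 440 with a filter of at least 1 CPM in every library of 1 group, against 670, and that filter tests fewer genes. Lower counts were not confined to falls. Over the 23 alternatives, rises of at least 2-fold numbered 347 to 554, against 504. All changes of at least 2-fold numbered 787 to 1283, against 1174. Of the lists, 11 passed in the main test and 20 by fry, which does not compare a list with other genes. By camera with an estimated correlation 0 passed (7 at an unadjusted p under 0.05), and the cause of this loss was not tested. For 3 of the 11 lists, cholesterol synthesis, late granule and interferon, the estimates were negative (-0.014, -0.014 and -0.023), below the preset 0.01. Their unadjusted p (camera) still rose, from 6.81e-06 to 0.00787, from 0.00525 to 0.0339 and from 0.0048 to 0.0317. These values argue against correlation between genes as the cause of the loss in these 3 lists. Without 1 library, 11 to 14 lists passed. Camera passed 16 in each of the 5 edgeR settings, adding the primary granule, dendritic cell, eosinophil, lymphoid and cytokine receptor lists, and the mitosis list passed with the length and GC trend removed (8.05e-04). The 5 edgeR settings share reads and filter and differ only in scaling or dispersion. Their filter left fewer members of the dendritic cell, lymphoid and cytokine receptor lists than the main test. None of the 365 changed list members was called in the opposite direction, nor any list that passed, but 70 of these members lost their call in at least 1 alternative, 56 of them without 1 library. Of the genes taken by the naming rule, those were Epor, H1f2, Hprt and Tubb5, and H4c3 gained a call without a filter. The replicate block gave 5342 changed genes. Same-numbered shRen and shCebpa libraries had correlations of deviations of 0.0021, -0.053 and -0.040 across genes, so the numbers were not taken to pair the libraries. Across genes the log2 fold change had a Spearman rho of 0.27 with GC content and -0.04 with exonic length. Removing a trend on exonic length and GC content left 77.0% of the calls in place, with 0 in the opposite direction by limma. This trend as a whole cause is thus argued against, but a part in the smaller changes stays open. With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. Only 1 split, the real one, gave as many changed genes (5973, highest other 0 by limma, with up to 622 at an unadjusted p under 0.05), as many changed by at least 2-fold (1174, highest other 0), and as many lists (11, highest other 8). Every other split mixes the groups, which moves most of the group difference into the spread within its sides. Low gene counts there follow from any large group difference, whatever its cause. Part of the difference stays between the sides, so the list counts give no background level either. Depth limits genes with few reads: the log2 scale with 1 added holds back their folds, and 10742 rows with a mean below 1 were not tested.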

Other observations

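The desmosome genes described first, the serpin genes, and the tests of scaling and of a replaced cell population were chosen after the results were seen. Some genes of the desmosome, the junction that ties epithelial cells together, had large falls. Dsp, Dsg2 and Pkp2 were seen first, and the others were then looked up. Of the 8 others tested, 3 fell (limma), against 22.2% of all genes tested, and no enrichment was tested. Desmoplakin (Dsp) fell from 87.7 ± 7.33 to 4.13 ± 1.9 (SD, n = 3 each; 21.3-fold lower), the plakophilin Pkp2 from 104.7 ± 3.42 to 6.73 ± 2.09 (15.6-fold lower) and the cadherin Dsg2 from 824 ± 49.1 to 116 ± 9.03 (7.13-fold lower). Dsc1 was 3.44-fold lower, Dsc2 2.45-fold and Perp 1.22-fold. Plakoglobin (Jup), at 3573 ± 365 and 3319 ± 298, did not pass (limma, adjusted p = 0.264), nor did Pkp3, Pkp4, Ppl and Evpl.

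On chromosome 1, 3 clade B serpin genes that lie in a row rose together. Serpinb2 (107500892 to 107525600 in GRCm38) had a log2 fold change of 3.58, Serpinb10 (107528994 to 107560742) of 4.31 and Serpinb8 (107589926 to 107608978) of 3.46. Their levels in shRen were low, at 37.4, 6.41 and 8.82, against 453, 136.8 and 92.7 in shCebpa.

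Neighbouring genes changed together beyond this cluster. Over 11035 adjacent pairs among 11056 genes with a mean value of at least 20, the correlation of log2 fold changes was 0.15 across pairs, which are not independent replicates, against at most 0.029 in 1000 shuffles. Reads shared by overlapping genes or by paralogs with like symbols are argued against as the whole cause, since the correlation was still 0.117 (highest shuffled 0.032) in the 9572 pairs without overlap or a shared symbol stem. A trend with exonic length and GC content is argued against likewise, at 0.0957 once it was removed (highest shuffled 0.031). Pairs under 50 kb apart exceeded pairs over 200 kb apart by 0.143 (spread 0.0277), so a candidate explanation is a regional effect on adjacent genes; transcription running past gene ends was not tested and stays open.

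The fall of mast cell and basophil genes may be a change within cells or a change in the mix of cells. The choice of scaling is argued against, since the list median stayed between -1.21 and -1.15 on the log2 scale over 7 scalings. A replacement of one population by another that lacks these transcripts, with no change within cells, would leave them no more than is left of the largest falls, which is at most 5.46% for the 10 named genes. The median percent left over the 18 list members was 44.4% (95% interval by order statistics 16.0% to 74.2%), and the lowest member kept 8.71%. The 10 genes were picked as the largest falls, so a list without members among them lies above them largely by that choice. Whether another population would lack all 18 transcripts is also not known. The comparison shows only that the list kept more than those 10 genes, and it cannot decide on that replacement. A population without any of the 18 transcripts would, however, leave every member the same share of its shRen level. The members' log2 fold changes had an SD of 1.22, against a median standard error of 0.088 over all genes, and Tpsab1 rose. For this list these values argue against that strict form. A replacement by a population that carries some of these transcripts stays open, as does a mix that changed among populations that all carry these transcripts, or several changes at once. So does the knockdown itself, the biological difference between the groups.

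A hairpin can also repress other transcripts through a short seed match in their 3′ UTR, and a hairpin against Cebpa has a seed whose matching site occurs in the Cebpa mRNA. All 7-base sequences of that mRNA found in at least 50 genes (2191) were searched in 12515 annotated 3′ UTRs, with UTR length and GC content taken into account. Among 2884 fallen genes the most enriched sequence was carried by 24.2%, against 20.1% predicted, an excess of 4.11 percentage points (SE 0.684). The largest excess in 1 shuffle of the fold changes was 2.09. Among 604 genes that fell by at least 2-fold the largest excess was 5.38 (SE 1.29). With 2 standard errors added, the excess was 5.48 percentage points among all fallen genes and 7.97 among those 604. Both lie below the 10 set in advance, so direct repression through such a seed is argued against as the whole cause of the fall of these sets. A contribution to part of the falls was not excluded. The sequence most associated with lower fold changes among 16063 tested (z = -6.49) was 1 of those in the Cebpa mRNA. Its excess was 4.11 percentage points among all fallen genes and 2.82 among those that fell by at least 2-fold. In 1 shuffle of the fold changes the lowest z was -3.97, taken over the 2191 sequences of the Cebpa mRNA only. Sequences of the Cebpa mRNA make up 13.6% of the sequences tested, so the match alone is little evidence for such a contribution. Effects that follow from an off-target hit on a regulator were not tested, and the hairpin's own sequence was not used here. Sequences complementary to the Cebpa mRNA, which the other strand of a hairpin could match, were not searched as a set.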
